A study of Mus musculus with 12 samples.

How the data were processed

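RNA of sorted dentate gyrus cells from 8-week-old LPA1-GFP reporter mice was sequenced in 12 libraries. Per the labels' protocols, cells were sorted by fluorescence from fresh tissue, RNA was extracted with a column kit, RNA of 1000 cells was amplified with a polymerase, and Illumina libraries were prepared. The groups were taken from the markers in the labels. Stem libraries held cells positive for LPA1-GFP, EGFR and Prominin-1. Progenitor libraries held the other 3 marker combinations of GFP-positive cells, and niche libraries held GFP-negative cells. Each group had 4 replicates.

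The deposited table, per its name, holds processed counts, but its values are on a log2 scale. They were read as log2(RPKM + 1), where RPKM is the read count per kilobase of exon, scaled to the library total. After the log was undone, 100% of the values above 0 were whole numbers of reads within a tolerance of 1e-05 reads. The exon length equalled the annotated length for 1235 genes. For 9275 it was found from the values as a length that made the reads of every library whole, so wholeness is a weaker check for these. The table listed 10749 Ensembl genes, of which 239 were at 0 in every library and 10510 were above 0 in at least 1. Per the submitters' processing notes, the genome build was GRCm38 (mm10). The aligner, the counter, its use of strand and the rule by which genes were listed are not given in the sources used here. Of the listed identifiers, 10579 matched a gene symbol and 10589 a position in the GENCODE annotation of GRCm38. No batch, lane or date is given in the labels.

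Library totals recovered from the deposited log2 values ran from 7597256 to 22854036 reads and equalled the sum over the listed genes (99.9989% to 100.0019%). The floor of 3 reads corresponded to 0.131 to 0.395 CPM (counts per library scaled to a common total). The reads came from amplified RNA without molecular identifiers, so such floors cover counting error only and not the sampling of molecules before amplification. Pairs of replicates were compared by a chi-square statistic of their recovered reads over genes, divided by its degrees of freedom. The lowest ratios were 39.8 in stem, 44.6 in progenitor and 123 in niche, so no pair lay within sampling noise. Since 2 amplifications of the same RNA could differ as much, this does not show that the libraries are independent. Each was counted as 1 replicate because the labels list it as a separate sample.

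A count test had been planned before the data were examined. Since the deposited values were log2 RPKM and not counts, limma was used instead, with the planned groups, libraries and covariates. Genes were kept when at least 4 libraries reached 10 reads per median library (a CPM of 0.767) and the total reached 15 reads, which left 8361 genes. Scaling factors were trimmed means of M-values (TMM) on the recovered reads. RPKM values were divided by these factors, a pseudocount of 1 RPKM was added, and log2 values were fitted with 1 mean per group over all 12 libraries. limma's empirical Bayes test was run with an intensity trend and robust spread, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. All adjusted p-values for genes below come from this test. Fold changes are differences on the log2(value + pseudocount) scale with their standard errors (SE), which understates the change of genes with low values. Levels are TMM-scaled RPKM as mean ± SD over n = 4 libraries.

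31 gene lists were written before the data were examined. They cover the sort markers, neural stem and radial glia, cell cycle, neuronal progenitors and neuroblasts, mature neurons, interneurons, astrocytes, oligodendrocyte precursors, oligodendrocytes, microglia and macrophages, endothelial cells, mural cells, fibroblasts and meninges, ependyma and choroid plexus, and blood cells. The functional lists cover presentation by major histocompatibility complex (MHC) class I and class II, complement, interferon response, Toll-like receptor and NF-kB signalling, chemokines and cytokine receptors, leukocyte surface and Fc receptors, lysosome and phagocytosis, LPA signalling, ErbB signalling, Notch signalling, immediate early and dissociation genes, lipid synthesis, glycolysis, cytosolic ribosomal proteins and mitochondrially encoded genes. Many list members were not in the deposited table. It held 16 of 33 microglia and macrophage genes, 17 of 40 cell cycle genes and 17 of 34 neural stem and radial glia genes. For neuroblasts it held 11 of 31 and for blood cells 9 of 30. Counts of list genes below cover the tested genes only. The 30 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists by the Benjamini-Hochberg method, two-sided. The test was repeated with a correlation estimated from the data. 4 further lists, of border macrophages, microglia, genes abundant in all macrophages and red cells, were written after the first results were seen.

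Genes were named by a rule fixed before the data were examined. It took the sort markers and, per comparison, the 10 largest changes in each direction among genes past the threshold whose CPM did not overlap between the groups and averaged at least 20 in the higher group. It also took up to 4 members of each list with the smallest adjusted p, in the direction of the list where it was called. For genes set apart in stem from both other groups, it took the 10 with the largest smaller change.

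The design text states that the 3 populations came from each of 4 replicates, so equal replicate numbers were taken as pairs and a fit with the replicate as a block was run beside the unblocked one. The check of this pairing was the correlation, across genes, of deviations from the group means for libraries with equal numbers. For replicates 1 to 4 it was -0.13, 0.07, -0.01 and 0.00 between stem and progenitor, -0.09, 0.04, 0.02 and 0.01 between stem and niche, and 0.17, 0.03, 0.21 and 0.09 between progenitor and niche. The highest correlation with a library of another number was 0.14, 0.02, 0.08 and 0.02 between stem and progenitor. It was 0.08, 0.03, 0.05 and 0.01 between stem and niche, and 0.02, 0.13, 0.1 and 0.11 between progenitor and niche. Genes are not independent replicates.

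Other settings, fixed before the data were examined, were median-of-ratios and library-size scaling, no filter, a stricter filter (CPM of at least 5), voom with sample quality weights on the recovered reads, fits of the compared groups alone, a spread estimate that was not robust, an estimated correlation for the lists, and each replicate left out in turn. Lists were not tested with voom or with the spread estimate that was not robust. Pseudocounts of 0.1 and 4 RPKM, and a fit without the 2 libraries that stood apart, were added after seeing the data.

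The test was checked on simulated data drawn from the real means and depths, with 50 genes changed at each of 4 sizes. For 4-, 8-, 16- and 32-fold changes, it recovered 13, 34, 34 and 42 of 50 between stem and progenitor, 14, 21, 34 and 42 between stem and niche, and 18, 31, 43 and 44 between progenitor and niche. It called 7 of 8020, 6 of 8020 and 10 of 8002 unchanged genes, respectively, and 0 genes in the wrong direction. In each comparison it called the planted list and 0 of 30 random lists. Genes were drawn independently of each other, so this does not show how often lists of correlated genes are called falsely. Scaling factors were recovered within 2.41%. The simulated libraries shared a common composition apart from the changed genes, while the real TMM factors ran from 0.418 to 1.25. So neither this value nor the counts of calls test the scaling between libraries as unlike as the real ones. The work used R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.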

Results

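The series asks how cells of the adult mouse dentate gyrus that carry the lysophosphatidic acid receptor LPA1 differ in their RNA, and its title speaks of an immune cell-related profile of the stem cells. A green fluorescent protein (GFP) reporter of the receptor gene was combined with the surface markers EGFR, a growth factor receptor, and Prominin-1, a membrane glycoprotein. This gave a stem population (positive for all 3), a progenitor population (GFP-positive, lacking 1 or both of the other markers) and a niche population (GFP-negative), with n = 4 libraries each. The labels do not say whether a replicate was an animal or a pool of animals, so p-values measure the spread between these libraries, part of which may be technical. Depth was 8693282, 10378625, 12948644 and 12175749 reads in stem replicates 1 to 4, 14873117, 15734860, 19940796 and 22854036 in progenitor and 12141396, 19237487, 13113096 and 7597256 in niche. Between 8037 and 9700 genes were above 0 per library.

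Libraries grouped by population, with 2 exceptions. The first principal component took 34.8% of the variance, the second 22.1% and the third 16.1%. Niche replicate 1 lay at 107.6 on the second component against -56.7 to -46.1 for the other niche libraries, and progenitor replicate 1 at -80.7 on the third against -37.1 to -31.7. Spearman correlations across genes between replicates were 0.909 to 0.944 in stem, 0.848 to 0.977 in progenitor and 0.718 to 0.841 in niche. The 2 alpha-globin genes, Hba-a1 and Hba-a2, took 33.0%, 10.9%, 2.62% and 6.81% of the reads of niche replicates 1 to 4, but at most 0.186% in stem and 0.228% in progenitor. Mitochondrially encoded genes took 21.8% ± 4.65 of reads in niche, 11.2% ± 0.963 in stem and 12.5% ± 2.19 in progenitor (SD, n = 4). These are shares of the reads of the listed genes and not of all reads sequenced. Genes such as Hbb-bs and Hbb-bt of red cells were not found among the listed ones. Scaling mattered for comparisons with niche: by library size alone, the median log2 fold change of all genes rose from 0.09 to 0.58 for stem against niche and from 0.15 to 0.62 for progenitor against niche. Changes are reported relative to the TMM scaling.

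**Figure D1:**
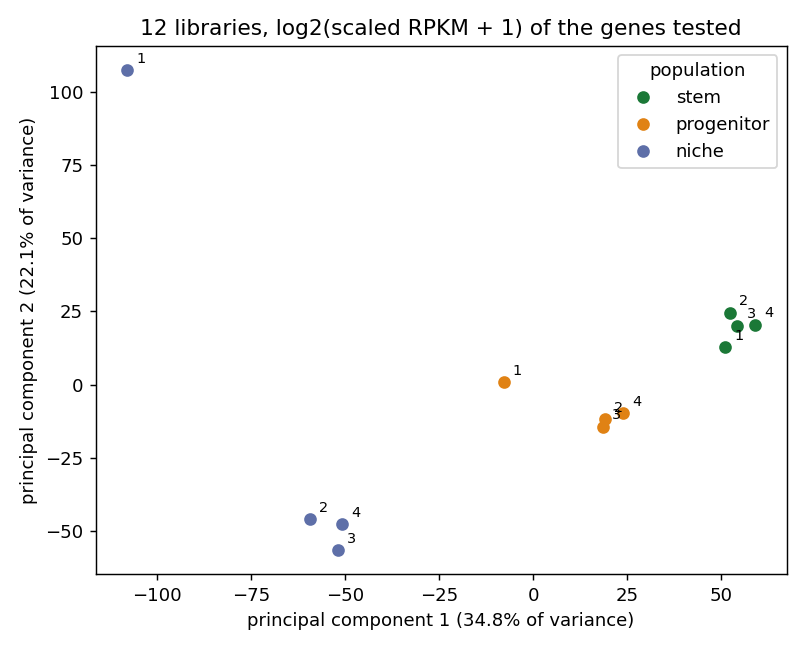
Principal components 1 and 2 of log2(scaled RPKM + 1) over the tested genes, with each point 1 library, coloured by population and marked with its replicate number, and axes giving component scores. The first component took 34.8% and the second 22.1% of the variance, and niche replicate 1 lay at 107.6 on the second, apart from the other 3 niche libraries.

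Egfr, the only sort marker among the tested genes, was higher in stem than in the other populations (Lpar1 and Prom1 were not analysed here). Egfr (ENSMUSG00000020122, GRCm38 chromosome 11, 16752203 to 16918158) encodes the receptor for epidermal growth factor. Its level was 34.1 ± 6.34 in stem, 5.60 ± 3.92 in progenitor and 8.51 ± 9.51 in niche. The log2 fold change was 2.64 ± 0.68 against progenitor (SE, limma adjusted p = 0.0272) and 2.45 ± 0.68 against niche (0.0181), and progenitor and niche differed by -0.19 ± 0.68 (0.892). The gene served to sort the cells, so its change is no finding between them. The first call was lost without stem replicate 1 (adjusted p = 0.0789), 2 (0.0613), 3 (0.0754) or 4 (0.0725) and without progenitor replicate 1 (0.101) or 3 (0.0760). The second was lost without stem replicate 1 (0.0501) or 3 (0.0521) and without niche replicate 3 (0.060) or 4 (0.0532). With a pseudocount of 0.1 RPKM the adjusted p against progenitor was 0.0508, within a range of 1.0e-05 to 0.101 over the alternatives run.

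Stem against progenitor compared GFP-positive cells that carried both other markers with those that did not. Stem libraries were rich in transcripts of macrophages and of dividing cells, while transcripts of young neurons, astrocytes, oligodendrocytes and mural cells were lower. Csf1r, the macrophage growth factor receptor (ENSMUSG00000024621, chromosome 18, 61100598 to 61132149), was at 549 ± 332 in stem and 19.1 ± 9.82 in progenitor, a log2 fold change of 4.78 ± 0.45 (SE, limma adjusted p = 2.5e-05). Stmn2, a microtubule regulator of young neurons (ENSMUSG00000027500, chromosome 3, 8509360 to 8561606), was at 2.41 ± 1.34 against 232 ± 96.1, a change of -6.11 ± 0.40 (7.7e-07). Of 8361 genes, 310 were higher and 284 lower in stem.

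The microglia and macrophage list had 33 genes, of which 16 could be tested. All 16 were higher in stem, and all 16 when adjusted over the list alone, with a median log2 fold change of 3.67 (camera adjusted p = 2.7e-29). Examples besides Csf1r were Mrc1, the macrophage mannose receptor (4.99 ± 0.50), Tyrobp, a signalling adaptor of myeloid cells (4.04 ± 0.41), and the protease gene Ctss (3.75 ± 0.40). Of 22 leukocyte surface and Fc receptor genes, 18 were higher and 4 not called (19 adjusted over the list alone, median 3.25, adjusted p = 1.9e-24). They included Trem2 (3.60 ± 0.38) and Cd48 (4.59 ± 0.66). The list also held Lcp1 (4.35 ± 0.56), whose protein lies inside the cell and is no surface receptor. Both lists also passed with an estimated correlation (adjusted p = 0.0263 each). Other genes among the largest changes were also known from macrophages: Mmp9, a matrix metalloproteinase, at 128 ± 74.3 against 1.61 ± 0.969 (5.55 ± 0.61), Adgre1, which encodes the F4/80 antigen (5.13 ± 0.69), and the lectin genes Cd209g (5.24 ± 0.63), Clec10a (5.05 ± 0.70) and Clec4n (4.91 ± 0.68). The spread of these genes within stem was wide. The median level of the macrophage list was 7.67 on the log2 scale in stem replicate 2 and 5.88 to 6.52 in the other 3 stem libraries. The pseudogene Gm11771 (5.23 ± 0.72) may share reads with its parent gene, so its value is uncertain.

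Other immune lists and the immediate early list were also higher in stem, but their calls were lost with an estimated correlation. Of 27 chemokine and cytokine receptor genes, 13 were higher and 1 lower (14 and 1 adjusted over the list alone, median 1.47, camera adjusted p = 1.8e-08, adjusted p = 0.0612 with an estimated correlation). The median was 0.94 without stem replicate 3 and 0.84 without progenitor replicate 3. Ccl7 and Ccl2, which attract monocytes, changed by 4.40 ± 0.79 and 3.98 ± 0.74. Of 14 Toll-like receptor and NF-kB genes, 7 were higher, 7 of them adjusted over the list alone (median 1.57, adjusted p = 1.6e-07, adjusted p = 0.0612 with an estimated correlation), with Tlr4, the endotoxin receptor, at 3.76 ± 0.59. Of 20 lysosome and phagocytosis genes, 9 were higher, 9 adjusted over the list alone (median 0.87, adjusted p = 2.6e-08, adjusted p = 0.0641 with an estimated correlation), among them Ctsc (4.45 ± 0.48) and Grn (2.87 ± 0.36). For MHC class I presentation, 2 of 14 were higher, 8 adjusted over the list alone (median 1.43, adjusted p = 7.2e-07, adjusted p = 0.0612 with an estimated correlation), and Psmb8, an immunoproteasome subunit, changed by 2.17 ± 0.46. For MHC class II presentation, 2 of 12 were higher, 3 adjusted over the list alone (median 0.92, adjusted p = 0.000894, adjusted p = 0.138 with an estimated correlation). The 2 were Ctss and Cd80, a costimulatory ligand (2.38 ± 0.40), and the median was 0.52 without stem replicate 2. Of 26 interferon response genes, 4 were higher and 1 lower (6 and 1 adjusted over the list alone, median 1.07, adjusted p = 0.000261, adjusted p = 0.104 with an estimated correlation), and the median was 0.64 without progenitor replicate 1. Of 13 immediate early and dissociation genes, 6 were higher, 7 adjusted over the list alone (median 1.68, adjusted p = 3.9e-07, adjusted p = 0.0641 with an estimated correlation), among them Ier3 (4.07 ± 0.68) and Egr2 (2.66 ± 0.55).

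Cell cycle genes were higher in stem in 13 of 17 cases, 14 adjusted over the list alone, with a median log2 fold change of 1.83 (camera adjusted p = 2.2e-14, adjusted p = 0.0321 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase (ENSMUSG00000020649, chromosome 12, 24708241 to 24714146), was at 339 ± 88.6 in stem and 87.0 ± 33.6 in progenitor (2.02 ± 0.37). The mitotic kinase gene Plk1 changed by 2.70 ± 0.47. Genes of neuronal progenitors and neuroblasts were lower in 4 of 11 cases, 5 adjusted over the list alone (median -0.82, adjusted p = 1.1e-07, adjusted p = 0.0263 with an estimated correlation). The 4 were Stmn2, Tubb3, a neuronal tubulin (-4.04 ± 0.37), the neuropeptide gene Tac2 (-5.69 ± 0.66) and Cd24a (-4.52 ± 0.56). Of 15 astrocyte genes, 11 were lower, 14 adjusted over the list alone (median -1.55, adjusted p = 1.3e-15, adjusted p = 0.0263 with an estimated correlation), with Aldoc at 241 ± 76.3 against 1600 ± 205 (-2.78 ± 0.27) and Clu at -2.71 ± 0.33. Of 12 oligodendrocyte genes, 10 were lower, 11 adjusted over the list alone (median -3.49, adjusted p = 5.9e-17, adjusted p = 0.0321 with an estimated correlation). Car2 changed by -3.28 ± 0.40. Of 10 mural cell genes, 6 were lower, 7 adjusted over the list alone (median -2.77, adjusted p = 3.9e-07, adjusted p = 0.0263 with an estimated correlation), with the pericyte marker Rgs5 at -3.57 ± 0.60. The median level of the mural list in progenitor replicate 1 was 6.05, against 4.96 to 5.09 in the other 3.

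Fibroblast and meninges genes were lower in 5 of 12 cases, 8 adjusted over the list alone (median -1.84, camera adjusted p = 1.7e-07, adjusted p = 0.0677 with an estimated correlation), among them the collagen gene Col1a2 (-2.62 ± 0.59). Of 8 ependyma and choroid plexus genes, 3 were lower, 3 adjusted over the list alone (median -1.53, adjusted p = 0.000218, adjusted p = 0.0641 with an estimated correlation): Ccdc153 (-2.87 ± 0.47), Sntn (-1.74 ± 0.36) and Ttr (-2.44 ± 0.55). Lipid synthesis genes were lower as a list with 1 of 16 called, also adjusted over the list alone (median -0.60, adjusted p = 0.0140, adjusted p = 0.131 with an estimated correlation). The neural stem and radial glia list was not called, with 0 of 17 higher and 2 lower (1 and 4 adjusted over the list alone, median -0.25, adjusted p = 0.130). Id4 of this list, an inhibitor of helix-loop-helix transcription factors, changed by -2.07 ± 0.38. The endothelial list was not called (0 of 15 higher, 1 lower, adjusted p = 0.102), but was called lower with the replicate block (0.0314), without stem replicate 1 (0.0268) and without progenitor replicate 3 (0.0448), within a range of 0.0268 to 0.523 over the alternatives run for lists. The ErbB list (2 of 7 higher, adjusted p = 0.0620) was called with no filter (0.0434), with a pseudocount of 4 RPKM (0.0492) and without stem replicate 3 (0.0421), stem replicate 4 (0.0388) or progenitor replicate 4 (0.0393), within a range of 0.0388 to 0.156. The cytosolic ribosomal protein list had 0 of 29 genes called and a median of -0.07 against a mean of -0.01, with the test pointing up (adjusted p = 0.953). It was called higher in stem without progenitor replicate 1 (0.00462), whose median level for this list was 10.6 against 9.47 to 9.52 in the other 3 progenitor libraries, and without niche replicate 1 as well (0.000295, range over the same alternatives 0.000295 to 0.997). The count of 594 genes dropped to 360 without stem replicate 2, the library with the highest macrophage values. Without any other single stem or progenitor library it dropped too, to between 403 and 477, so a drop was not particular to stem replicate 2. The count was 1130 without progenitor replicate 1 and niche replicate 1 (573 shared), 1421 with only these 2 groups in the fit (592 shared) and 2689 with voom on the recovered reads (594 shared).

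**Figure D2:**
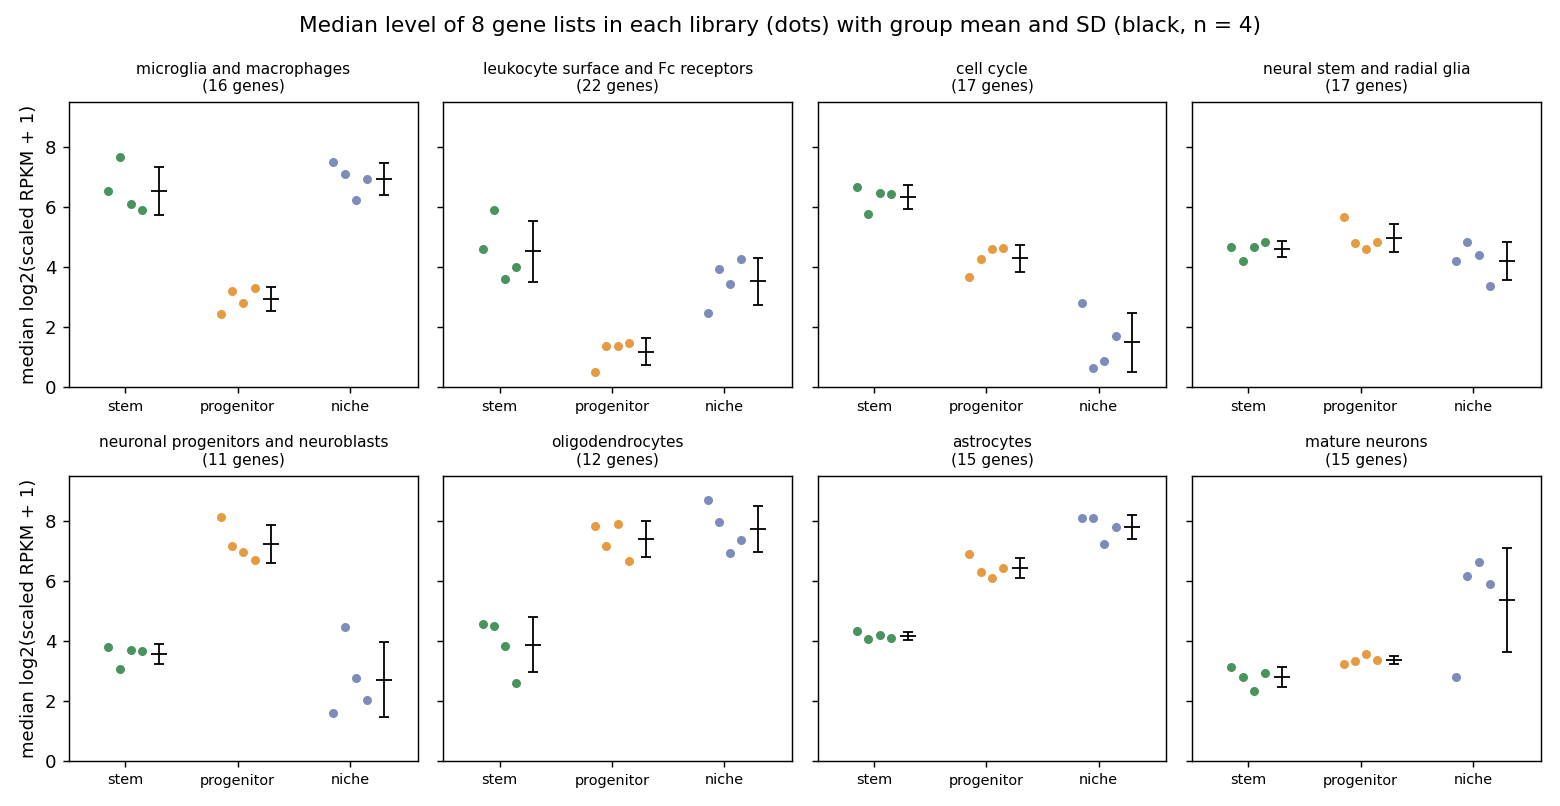
Median log2(scaled RPKM + 1) of 8 gene lists in each library, as coloured dots for replicates 1 to 4 from left to right, with the mean ± SD of each population (n = 4) in black. The macrophage list averaged 6.54 in stem, 2.94 in progenitor and 6.94 in niche, and the cell cycle list 6.33, 4.29 and 1.495.

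Stem against niche compared the stem cells with all GFP-negative cells of the dentate gyrus. Cell cycle genes were higher in stem and astrocyte genes lower. Lists of mature neurons, oligodendrocytes, endothelial and mural cells were lower too, but lost their call with an estimated correlation. Rrm2 was at 339 ± 88.6 in stem and 7.56 ± 2.41 in niche, a log2 fold change of 5.32 ± 0.37 (SE, limma adjusted p = 3.0e-07). Ttr, the thyroid hormone carrier of the choroid plexus (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321), was at 38.8 ± 26.7 against 7362 ± 2460, a change of -7.75 ± 0.55 (3.0e-07). Of 8361 genes, 910 were higher and 896 lower in stem, but scaling by library size alone gave 2018 higher and 586 lower.

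All 17 cell cycle genes were higher in stem, also adjusted over the list alone, with a median of 4.36 (camera adjusted p = 2.9e-18, adjusted p = 0.0444 with an estimated correlation). Pclaf, a replication factor outside this list, was at 140 ± 35.5 against 1.94 ± 1.20 (5.64 ± 0.37). The neuroblast list was split, with 4 of 11 higher and 3 lower (6 and 3 adjusted over the list alone, median 0.94, adjusted p = 0.394). Eomes, a transcription factor of intermediate progenitors (ENSMUSG00000032446, chromosome 9, 118478212 to 118486132), was at 23.1 ± 5.74 against 0.732 ± 0.414 (3.80 ± 0.39), and Neurog2 changed by 3.18 ± 0.40, while Stmn2 was lower (-4.95 ± 0.40). The neural stem and radial glia list was split too, with 5 of 17 higher and 3 lower (8 and 4 adjusted over the list alone, median 0.77, adjusted p = 0.255). Sox1 changed by 2.94 ± 0.48, and Id3 by -4.00 ± 0.51.

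All 15 astrocyte genes were lower in stem, also adjusted over the list alone (median -2.95, camera adjusted p = 2.0e-17, adjusted p = 0.0444 with an estimated correlation), with S100b at 13.3 ± 4.85 against 235 ± 68.3 (-4.05 ± 0.36). The other lower lists lost their call with an estimated correlation. Of 12 oligodendrocyte genes, 11 were lower, 12 adjusted over the list alone (median -3.64, adjusted p = 3.8e-11, adjusted p = 0.0967 with an estimated correlation). Of 12 oligodendrocyte precursor genes, 8 were lower, 8 adjusted over the list alone (median -1.95, adjusted p = 1.6e-06, adjusted p = 0.0806 with an estimated correlation), among them Neu4 (-5.27 ± 0.44). Of 15 mature neuron genes, 13 were lower, 13 adjusted over the list alone (median -2.89, adjusted p = 6.9e-08, adjusted p = 0.196 with an estimated correlation). Snap25, of the synaptic release machinery, was at 7.36 ± 2.01 against 175 ± 75.3 (-4.32 ± 0.38). The median level of the list in niche replicate 1 was 2.79, within the 2.31 to 3.12 of the stem libraries, against 5.88 to 6.63 in the other 3 niche libraries, although Snap25 was at 92.2 in that library and 5.31 to 9.41 in stem. Of 6 interneuron genes, 4 were lower, 5 adjusted over the list alone (median -2.38, adjusted p = 0.00175, adjusted p = 0.196 with an estimated correlation). The median of niche replicate 1 again lay within stem (0.53 against 0.20 to 1.11 in stem and 3.33 to 4.53 in the other niche libraries). Of 15 endothelial genes, 11 were lower, 12 adjusted over the list alone (median -2.57, adjusted p = 2.1e-08, adjusted p = 0.0806 with an estimated correlation), with the glucose transporter gene Slc2a1 at -3.20 ± 0.43. Of 10 mural cell genes, 7 were lower, 9 adjusted over the list alone (median -2.65, adjusted p = 4.8e-05, adjusted p = 0.0806 with an estimated correlation).

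Blood cell genes were lower in stem in 3 of 5 cases, 4 adjusted over the list alone (median -6.88, camera adjusted p = 8.3e-05, adjusted p = 0.143 with an estimated correlation), and the median was -4.10 without niche replicate 1. Hba-a1 (ENSMUSG00000069919, chromosome 11, 32283511 to 32284465) changed by -8.30 ± 0.88 and Alas2, of haem synthesis in red cells, by -6.88 ± 0.75. Hba-a1 and Hba-a2 are near-identical copies, so the split of reads between them is uncertain. All 12 tested mitochondrially encoded genes were lower in stem, also adjusted over the list alone (median -1.58, adjusted p = 3.8e-11, adjusted p = 0.0545 with an estimated correlation), with mt-Nd1 at 3901 ± 363 against 17857 ± 2204 (-2.19 ± 0.19). The list stayed lower by library size alone (median -0.88). Of 10 glycolysis genes, 5 were lower, 7 adjusted over the list alone (median -0.91, adjusted p = 0.000319, adjusted p = 0.114 with an estimated correlation). The cytosolic ribosomal protein list had 0 of 29 genes called (median 0.12, adjusted p = 0.727), but was called higher in stem by library size alone (5.2e-06) and without niche replicate 1 (0.0472), the library with 33.0% alpha-globin reads, or without it and progenitor replicate 1 (0.00605, range over the alternatives run for lists 5.2e-06 to 0.992).

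The microglia and macrophage list was split, with 3 of 16 genes higher and 4 lower, also adjusted over the list alone (median -0.02 against a mean of 0.31, with the test pointing down, camera adjusted p = 0.850). Mrc1 (5.07 ± 0.50) and the scavenger receptor gene Cd163 (5.11 ± 0.60) were higher in stem. Siglech, a lectin gene of microglia (ENSMUSG00000051504, chromosome 7, 55768178 to 55778925), was lower, at 14.5 ± 8.19 against 154 ± 28.6 (-3.43 ± 0.44). Of 27 chemokine and cytokine receptor genes, 6 were higher and 5 lower (6 and 8 adjusted over the list alone, median -0.56 against a mean of 0.01, adjusted p = 0.558), with Ccl7 at 1015 ± 968 against 11.7 ± 7.93 (6.12 ± 0.79). Of 26 interferon response genes, 8 were higher and 2 lower, also adjusted over the list alone (median 0.75, adjusted p = 0.0484, adjusted p = 0.405 with an estimated correlation), with Ifit3 at 3.83 ± 0.52. The call of the interferon list was lost without stem replicate 2 (0.184), niche replicate 3 (0.125) or niche replicate 4 (0.102), by library size alone (0.0947), with only these 2 groups in the fit (0.0685) and with a pseudocount of 0.1 RPKM (0.0560), within a range of 0.00634 to 0.405. The median was 0.48 without stem replicate 2. Of 13 immediate early and dissociation genes, 5 were higher and 1 lower (6 and 1 adjusted over the list alone, median 1.41, adjusted p = 0.0391, adjusted p = 0.430 with an estimated correlation), with Fos at 798 ± 481 against 91.3 ± 60.7. The call of the immediate early list was lost by library size alone (0.0679), with no filter (0.0907), with a pseudocount of 0.1 RPKM (0.0532), without stem replicate 1 (0.0890), 2 (0.262) or 3 (0.0703) or niche replicate 1 (0.0930) or 3 (0.0897), and without both progenitor replicate 1 and niche replicate 1 (0.0509), within a range of 0.0202 to 0.430. The median was 0.84 without stem replicate 2. The MHC class II list was not called (1 of 12 higher, 4 lower, 1 and 5 adjusted over the list alone, adjusted p = 0.0574), but was called lower with the replicate block (0.0404), by library size alone (0.0161), with no filter (0.0495), with the stricter filter (0.0257), with a pseudocount of 4 RPKM (0.0438), and without stem replicate 2 (0.0127) or niche replicate 3 (0.0059), within a range of 0.0059 to 0.430. The Toll-like receptor and NF-kB list (2 of 14 higher, adjusted p = 0.0795) was called higher without niche replicate 4 (0.0405, range 0.0405 to 0.514).

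LPA signalling genes were lower as a list, with 1 of 7 higher and 4 lower, also adjusted over the list alone (median -1.75, camera adjusted p = 0.0431, adjusted p = 0.129 with an estimated correlation). The phosphatase gene Plpp3 and Plppr1 changed by -1.88 and -3.17. The call was lost with no filter (0.0567), with a pseudocount of 0.1 RPKM (0.0525), without stem replicate 1 (0.0569), 2 (0.0851) or 3 (0.0513) or niche replicate 1 (0.156, median -1.12) or 3 (0.0518), and without both progenitor replicate 1 and niche replicate 1 (0.1295), within a range of 0.0388 to 0.156. Of 8 ependyma and choroid plexus genes, 2 were lower, also adjusted over the list alone (median -0.53, adjusted p = 0.0484, adjusted p = 0.352 with an estimated correlation): Ttr and Kl (-2.83). The call of the ependyma list was lost with median-of-ratios scaling (0.0632), with the stricter filter (0.0557), with a pseudocount of 0.1 RPKM (0.0560), without stem replicate 3 (0.0513) or 4 (0.0540) or niche replicate 1 (0.162) or 3 (0.125), and without both progenitor replicate 1 and niche replicate 1 (0.203), within a range of 0.00864 to 0.352. Without niche replicates 1, 2, 3 or 4 the median was -0.84, -1.07, 0.00 and -1.06. The fibroblast and meninges list (1 of 12 higher, 2 lower, adjusted p = 0.0670) was called lower with the replicate block (0.0459), by library size alone (0.0260), and without stem replicate 1 (0.0377), stem replicate 3 (0.0168) or niche replicate 4 (0.0388), within a range of 0.0168 to 0.536. Lipid synthesis (0 of 16 higher, 3 lower, adjusted p = 0.0795) was called lower without niche replicate 4 (0.0422, range 0.0422 to 0.352). Among single genes past these lists, the processed pseudogene Gm15428 and the antisense transcript Gm14024 (5.54 ± 0.37) were among the largest increases. Their reads may belong to a parent or overlapping gene, since the use of strand is not stated. Without progenitor replicate 1 and niche replicate 1 the count of genes called rose from 1806 to 3025 (1734 shared).

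**Figure D3:**
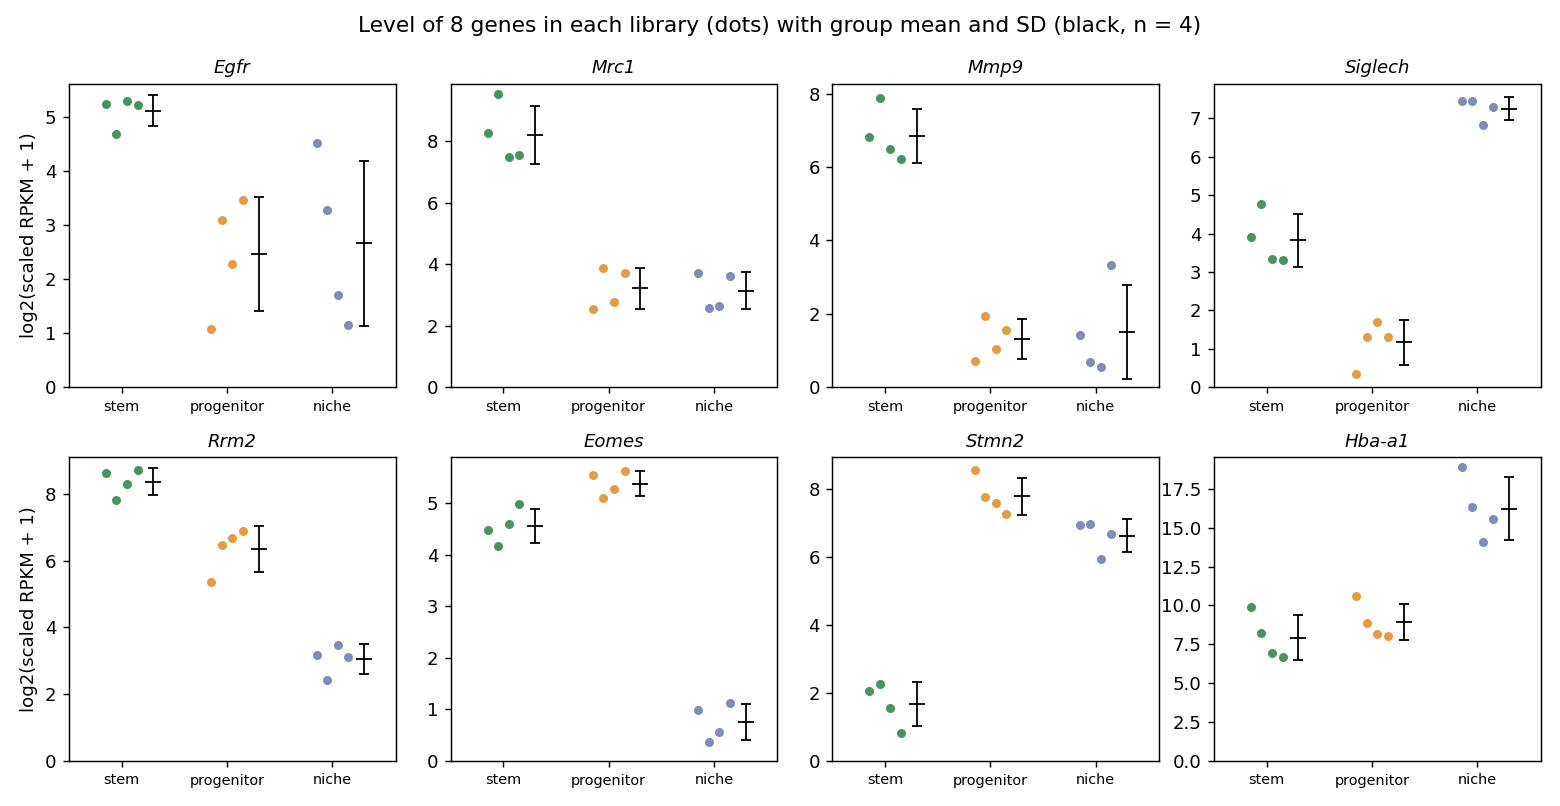
Level of 8 genes, as log2(scaled RPKM + 1), in each library, as coloured dots for replicates 1 to 4 from left to right, with the mean ± SD of each population (n = 4) in black. Mrc1 and Mmp9 were high in stem alone, Siglech in niche, Eomes in progenitor (41.3 scaled RPKM) and stem (23.1), and Hba-a1 in niche with a wide spread.

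Progenitor against niche compared the remaining GFP-positive cells with the GFP-negative cells. Progenitor libraries were richer in transcripts of neuroblasts and poorer in mitochondrially encoded ones. The cell cycle and neural stem lists were higher too, and the microglia, leukocyte, mature neuron and endothelial lists lower, but these 6 lost their call with an estimated correlation. Eomes was at 41.3 ± 7.02 in progenitor and 0.732 ± 0.414 in niche, a log2 fold change of 4.63 ± 0.39 (SE, limma adjusted p = 4.2e-06). Siglech was at 1.36 ± 0.813 against 154 ± 28.6, a change of -6.09 ± 0.44 (1.5e-06). Of 8361 genes, 473 were higher and 482 lower in progenitor, but scaling by library size alone gave 1525 higher and 314 lower.

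Neuronal progenitor and neuroblast genes were higher in 8 of 11 cases, 10 adjusted over the list alone (median 2.52, camera adjusted p = 7.5e-10, adjusted p = 0.0378 with an estimated correlation), among them Neurog2 (3.23), Tac2 (4.63 ± 0.66) and Tubb3 (2.52 ± 0.37). Cell cycle genes were higher in 14 of 17 cases, 16 adjusted over the list alone (median 2.56, adjusted p = 9.9e-13, adjusted p = 0.0546 with an estimated correlation), with Rrm2 at 3.30 ± 0.37 and Aurkb at 3.11. Of 17 neural stem and radial glia genes, 6 were higher and 1 lower (9 and 1 adjusted over the list alone, median 1.02, adjusted p = 0.0126, adjusted p = 0.213 with an estimated correlation). Fabp7, a fatty acid binding protein of radial glia, was at 1413 ± 527 against 500 ± 61.4 (1.43 ± 0.30). The call of this list was lost without progenitor replicate 1 (0.0562) or niche replicate 3 (0.103), within a range of 0.0035 to 0.213. The median was 0.63 without niche replicate 1. Outside the lists, Emx1, a transcription factor of cortex and hippocampus, was at 38.2 ± 12.1 against 1.74 ± 1.15 (3.89 ± 0.46), and Sfrp1, a Wnt antagonist, at 45.0 ± 9.07 against 3.49 ± 4.75 (3.84 ± 0.56). Hopxos (4.79) lies antisense within Hopx, so its reads cannot be told apart from those of Hopx without strand.

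Microglia and macrophage genes were lower in progenitor in 12 of 16 cases, 13 adjusted over the list alone (median -3.74, camera adjusted p = 8.4e-17, adjusted p = 0.0546 with an estimated correlation), with Ctss at 56.7 ± 12.5 against 2124 ± 664 (-5.17 ± 0.40) and Ly86 at 16.3 ± 9.59 against 829 ± 379 (-5.71 ± 0.55). Of 22 leukocyte surface and Fc receptor genes, 12 were lower, 15 adjusted over the list alone (median -2.51, adjusted p = 3.5e-13, adjusted p = 0.0546 with an estimated correlation), and the median level of this list was 0.51 in progenitor replicate 1 against 1.36 to 1.48 in the other 3. Of 20 lysosome and phagocytosis genes, 12 were lower, 14 adjusted over the list alone (median -1.32, adjusted p = 2.5e-10, adjusted p = 0.0583 with an estimated correlation), among them Laptm5 (-4.17). Of 27 chemokine and cytokine receptor genes, 10 were lower, while 2 were higher and 16 lower adjusted over the list alone (median -1.69, adjusted p = 3.5e-08, adjusted p = 0.0741 with an estimated correlation), with Csf1r at -3.93 ± 0.45. MHC class II genes were lower in 5 of 12 cases, 6 adjusted over the list alone (median -1.74, adjusted p = 6.7e-06, adjusted p = 0.0757 with an estimated correlation), and MHC class I genes in 2 of 14, also adjusted over the list alone (median -0.83, adjusted p = 0.000960, adjusted p = 0.138 with an estimated correlation). Examples were H2-DMa (-4.11) and B2m (-1.98), and the class II median was -2.77 without niche replicate 3. Toll-like receptor and NF-kB genes were lower in 1 of 14 cases, 3 adjusted over the list alone (median -0.97, adjusted p = 0.0108, adjusted p = 0.260 with an estimated correlation). The list median was 1.30 in niche replicate 1, below every progenitor library (1.34 to 1.69), against 2.58 to 2.89 in the other niche libraries. Complement genes were lower in 2 of 5 cases, 3 adjusted over the list alone (median -1.35, adjusted p = 0.0287, adjusted p = 0.132 with an estimated correlation), a call lost without progenitor replicate 1 (0.0530) or niche replicate 2 (0.0608), within a range of 0.0124 to 0.132.

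Mature neuron genes were lower in 8 of 15 cases, 10 adjusted over the list alone (median -2.55, camera adjusted p = 2.0e-09, adjusted p = 0.109 with an estimated correlation), with the vesicular glutamate transporter gene Slc17a7 at -4.71 ± 0.58 and Thy1 at -4.51. In niche replicate 1 the median level of this list, 2.79, lay below every progenitor library (3.24 to 3.56), against 5.88 to 6.63 in the other 3 niche libraries, although Slc17a7 was at 15.4 in that library and 0.216 to 2.38 in progenitor. Interneuron genes were lower in 1 of 6 cases, 4 adjusted over the list alone (median -1.38, adjusted p = 0.00119, adjusted p = 0.132 with an estimated correlation). The median of niche replicate 1, at 0.53, lay within the 0.17 to 1.56 of the progenitor libraries, against 3.33 to 4.53 in the other niche libraries. Endothelial genes were lower in 10 of 15 cases, 12 adjusted over the list alone (median -2.27, adjusted p = 7.1e-09, adjusted p = 0.0546 with an estimated correlation), with Slco1c1, a thyroid hormone transporter, at -2.16. Astrocyte genes were lower in 7 of 15 cases, 9 adjusted over the list alone (median -1.24, adjusted p = 9.8e-08, adjusted p = 0.0808 with an estimated correlation), with S100b at -3.23. Oligodendrocyte precursor genes were lower in 7 of 12 cases, 8 adjusted over the list alone (median -1.89, adjusted p = 1.4e-07, adjusted p = 0.0546 with an estimated correlation), while 0 of 12 oligodendrocyte genes were called (median -0.25, adjusted p = 0.419).

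Mitochondrially encoded genes were lower in progenitor in 11 of 12 cases, 12 adjusted over the list alone (median -1.52, camera adjusted p = 5.5e-14, adjusted p = 0.0378 with an estimated correlation), and by library size alone the median was -0.86. Blood cell genes were lower in 3 of 5 cases, also adjusted over the list alone (median -7.04, adjusted p = 1.8e-05, adjusted p = 0.0873 with an estimated correlation). That median was -4.30, -4.69, -4.48 and -4.63 without progenitor replicates 1 to 4, and -4.39 without niche replicate 1. Glycolysis genes were lower in 4 of 10 cases, 6 adjusted over the list alone (median -1.07, adjusted p = 0.000104, adjusted p = 0.0741 with an estimated correlation). The ErbB list was lower with 1 of 7 called, 2 adjusted over the list alone (median -1.13, adjusted p = 0.0291, adjusted p = 0.109 with an estimated correlation), a call lost without progenitor replicate 1 (0.0876), niche replicate 1 (0.0594, median -0.69) or niche replicate 2 (0.0569), or without both progenitor replicate 1 and niche replicate 1 (0.149), within a range of 0.014 to 0.149. Ribosomal protein genes were not called (0 of 29, median 0.13, adjusted p = 0.772), but were called higher by library size alone (1.7e-07) and without niche replicate 1 (0.0149), within a range of 1.7e-07 to 0.991. Without niche replicate 1 the count of genes called rose from 955 to 1658, and without progenitor replicate 2, 3 or 4 it dropped to 559, 536 and 546. Without both niche replicate 1 and progenitor replicate 1 it was 2020, of which 873 were shared.

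**Figure D4:**
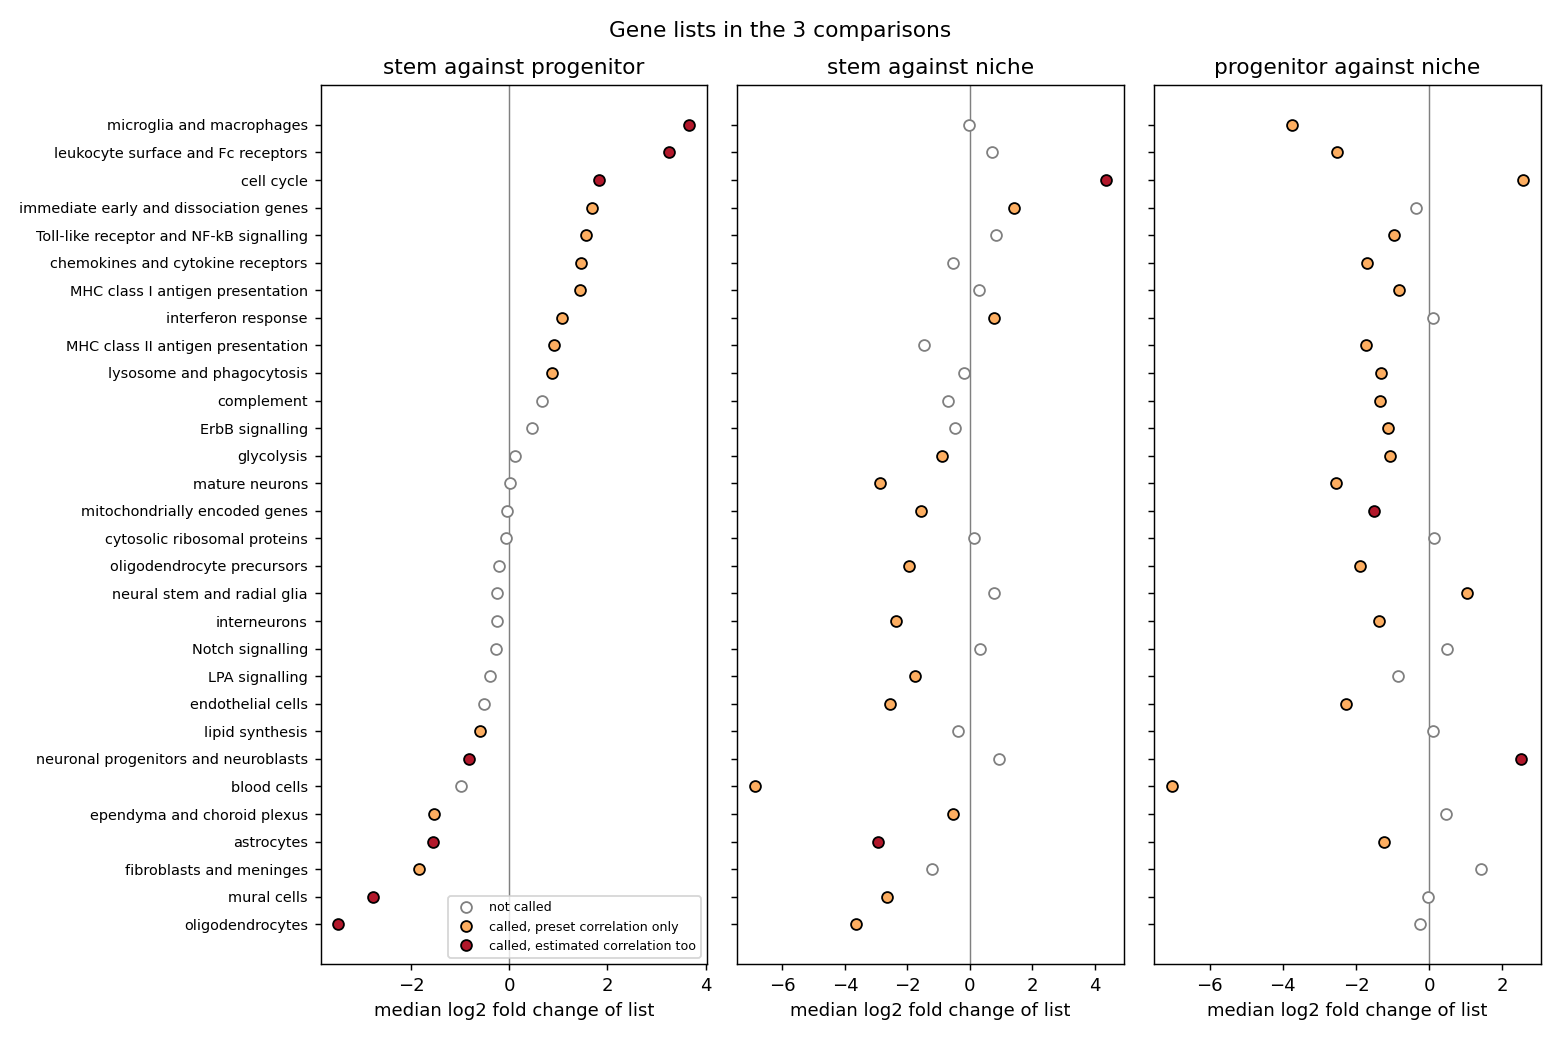
Median log2 fold change of the 30 tested gene lists in the 3 comparisons, with a point per list, white where the list was not called, orange where it was called with the preset correlation alone, and red where it was called with an estimated correlation too. The red points numbered 7 for stem against progenitor, 2 for stem against niche and 2 for progenitor against niche.

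Genes that set stem apart from both other populations were taken from the same tests. Stem libraries stood out by cell cycle genes and by some macrophage genes that were low in niche too, and had the lowest levels of most astrocyte and oligodendrocyte genes. Mrc1 (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057) was at 354 ± 264 in stem, 9.10 ± 4.45 in progenitor and 8.43 ± 3.83 in niche. Mmp9 (ENSMUSG00000017737, chromosome 2, 164940780 to 164955850) was at 128 ± 74.3, 1.61 ± 0.969 and 2.98 ± 4.12. In all, 178 genes were higher and 169 lower in stem than in both.

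The other genes with the largest smaller increase were Pla2g2d, a secreted phospholipase (log2 fold changes of 5.02 and 5.41), Gpx3, a glutathione peroxidase (4.66 and 4.75), Ms4a4a (4.72 and 5.87), Dab2, an endocytic adaptor (4.65 and 4.99), Cd209g, Clec10a, Clec4n and the pseudogene Gm11771. The decreases included Stmn2 (-6.11 and -4.95), Stmn4 (-4.13 and -4.44), Cldn11, a tight junction gene of myelin (-3.88 and -4.34), and the pericyte genes Higd1b (-4.41 and -4.90) and Vtn (-3.96 and -3.81). By list, the genes higher than in both included 13 of 17 cell cycle, 6 of 27 chemokine, 4 of 13 immediate early and 3 of 16 macrophage genes. Those lower than in both included 11 of 15 astrocyte, 10 of 12 oligodendrocyte, 4 of 10 mural and 3 of 11 neuroblast genes. Both comparisons share the stem libraries, and in 100 simulations of unchanged groups the highest overlap was 0 genes. Hardly any gene is called in such groups, so this value says nothing on the overlap that shared libraries give to changed genes. Independent lists with the same numbers of calls would share 33.7 and 30.4 genes. When the stem libraries were divided between the comparisons (6 ways), 45 to 64 genes were higher and 52 to 99 lower, against 3.74 to 14.7 and 4.42 to 8.40 for independent lists. Both comparisons still shared the scaling and the spread estimate of each gene, which can raise the overlap. The figures for independent lists also take every tested gene as equally likely to be called. The higher set counted 114 genes without stem replicate 1 and 310 without niche replicate 1. The lower set counted 107 and 110 without stem replicate 2 or 4, and 369 without niche replicate 1. Without progenitor replicate 1 and niche replicate 1 together, 320 genes were higher and 392 lower than in both (166 shared each).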

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

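The tests of the macrophage genes, of the red cell genes and of the libraries that stood apart were chosen after the results were seen, while the test of alpha-globin and scaling was set before. Of 276 groups of 4 libraries examined (depth measures, list medians and named genes), 17 (6.16%) held a library whose gap to the nearest other, divided by the group's range, passed Dixon's 95% critical value for 4 values. Chance flags about 1 in 20 groups. Stem replicate 2 was the library in 6 of them and progenitor replicate 1 in 6.

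In stem replicate 2, Clec10a stood at 8.83 on the log2 scale against 6.99 to 7.20 in the other stem libraries (gap ratio 0.887), Clec4n at 7.87 against 6.06 to 6.21 (0.915), and the Toll-like receptor and NF-kB list at 4.13 against 2.98 to 3.10 (0.897). Lower in that library were Egfr, at 4.69 against 5.22 to 5.31 (0.866), the LPA signalling list, at 2.64 against 3.12 to 3.20 (0.851), and the glycolysis list, at 7.03 against 7.46 to 7.49 (0.92).

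The higher of these values go with a wider pattern, macrophage genes high in all stem libraries and highest in stem replicate 2. Whether the lower ones belong to it was not tested. Microglia like those of niche, as the only source, are argued against: such a source would keep 1 difference from niche over the 16 genes of the fixed macrophage list, but their differences had an SD of 2.4508 against a median SE of 0.52, with 3 genes higher and 4 lower in stem. Microglia as a part of the source were not excluded. RNA of macrophages sorted with the stem cells and stem cells that carry these transcripts themselves cannot be told apart: the median difference from progenitor of 3.672 over the fixed list comes from pooled cells, and a pooled library cannot tell which cell held which transcript. The gate named in the labels used only GFP, EGFR and Prominin-1, with no macrophage marker for exclusion. The lists written after the pattern was seen overlap with the fixed list (3 of 13 border macrophage, 3 of 6 microglia and 7 of 12 genes abundant in all macrophages), so they describe it and decide nothing. Of the border genes 12 were higher than in progenitor and 11 than in niche (median 4.65 and 4.75), of the microglia genes 4 were higher than in progenitor and all 6 lower than in niche (2.92 and -2.89), and of the abundant genes 11 were higher than in progenitor while 2 were lower than in niche (3.3097 and 0.17). Within stem, 1 offset per library took 90.4% of the variance of the 25 border and abundant genes (at most 45.0% in 10000 random lists). Of 34 neural and cell cycle genes 31 went the other way, against 55.1% of all tested genes. Both origins allow this too.

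In progenitor replicate 1, 8455 genes were above 0 against 9608 to 9700 in its group (gap ratio 0.926), the TMM factor was 0.917 against 1.24 to 1.25 (0.973), and Vtn stood at 10.2 against 8.93 to 9.12 (0.847). Its medians also stood apart for the mural list, 6.05 against 4.96 to 5.09 (0.886), the leukocyte list, 0.51 against 1.36 to 1.48 (0.875), and the cytosolic ribosomal protein list, 10.6 against 9.47 to 9.52 (0.958). In niche replicate 1, Csf1r stood at 7.56 against 8.23 to 8.30 (0.903) and Gpx3 at 3.13 against 4.03 to 4.16 (0.876).

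Both libraries stood apart from their groups across many genes. They bear the same replicate number, and their deviations correlated at 0.17 across genes. Progenitor replicate 1 reached at most 0.02 with another niche library. Whether the 2 libraries share a cause was not tested. For progenitor replicate 1, lower depth is argued against, since each other library of its group, thinned to as many reads outside alpha-globin, still showed at least 1083.8 more genes. A loss of molecules stays open: its spread in the top 10% of genes by level was 3.372 times that of the next library (95% interval 2.944 to 3.774), which a loss and other causes can both give. Gene length may go with it: its deviation correlated with gene length across genes at -0.3992 (Spearman), against at most 0.0498 in size in the rest of its group, although stem replicate 1, which did not stand apart, reached 0.3601. For niche replicate 1, depth (112.9 more genes) and a length bias of its own (-0.221, with up to 0.2355 in size in another niche library) were argued against, and a loss of molecules stays open for the same reason (1.858, 1.674 to 2.097). No biological explanation was tested, because the labels give none for a single library.

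The high share of alpha-globin reads in niche went with a median log2 difference between stem and niche that depended on scaling. With both alpha-globin genes taken out, the gap between library-size and TMM scaling was still 0.3942, so alpha-globin reads alone do not account for it. Red cells sorted with the niche cells remain possible but undecided: over 7 other red cell genes the median difference of stem from niche was -1.6488 with an SD of 2.57. Of these genes 4 were lower in stem and 0 higher, with differences from -6.88 for Alas2 to 0.82 for Ank1. Of all 9 tested genes of the red cell list, 6 were lower in stem than in niche (median -2.38) and 0 differed from progenitor (median 0.11).

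Further values that stood apart were the Notch signalling list in stem replicate 1, 3.17 against 3.37 to 3.40 (0.868), Neu4 in stem replicate 1, 1.19 against 0.02 to 0.15 (0.887), and the immediate early list in niche replicate 3, 3.56 against 3.86 to 3.91 (0.863).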

How the results depend on the processing

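The pseudocounts of 0.1 and 4 RPKM and the fit without both libraries that stood apart were chosen after seeing the data, and the other alternatives before. Median-of-ratios scaling, no filter, the stricter filter, the spread estimate that was not robust and a pseudocount of 4 RPKM kept all 5 gene counts within 1.5 times. With the replicate as a block the counts were 607, 1814 and 947 for stem against progenitor, stem against niche and progenitor against niche, and 184 and 170 for genes higher or lower in stem than in both (554, 1698, 871, 169 and 152 shared). The block gained the call of 6 and lost that of 3 of the 392 named gene results, and gained that of 3 of the 90 list results. Library size alone gave 1839 genes for progenitor against niche. Voom with quality weights gave 2689 for stem against progenitor (594 shared) and 1557 for progenitor against niche (802 shared), and 512 and 609 for genes higher or lower in stem than in both (141 and 162 shared). Fits of the 2 compared groups alone gave 1421, 539 and, for genes higher in stem than in both, 308. A pseudocount of 0.1 RPKM gave 115 genes higher in stem than in both. Without progenitor replicate 1 and niche replicate 1 together, the counts were 1130, 3025 and 2020, and 320 and 392 for higher or lower than in both (573, 1734, 873, 166 and 166 shared). With each replicate left out in turn, the counts ran from 360 to 477, 1279 to 2505 and 536 to 1658, from 114 to 310 for higher than in both and from 107 to 369 for lower. Fewer libraries lower the power of such fits, but the rise without niche replicate 1 goes the other way. The cause was not tested for any of the other changed counts. With an estimated correlation, 7, 2 and 2 lists were called in place of 17, 15 and 20, and with each replicate left out 17 to 18, 12 to 17 and 17 to 23. Among 7426 values of 392 named gene results, 6949 kept their side of the threshold, 293 lost the call (197 of them with 1 replicate left out), 184 gained it and 0 reversed. Among 1613 values of 90 list results, 1489 were kept, 80 lost the call (41 of them with an estimated correlation), 44 gained it and 0 reversed. Direction was compared only where the main or the alternative fit called the result, so a change of sign in uncalled results was not counted. For lists it was the direction of the test and not the sign of the median. The count test with its own size factors that had been listed beforehand was not run, since the deposited unit is log2 RPKM. The recovered reads would have allowed such a test, so its result is not known. Of the tests that take reads, only voom was run on the recovered ones. Lists were run neither with voom nor with the spread estimate that was not robust. Depth limits genes near the floor of 0.131 to 0.395 CPM, for which an absence of a call says little.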

Other observations

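The comparisons of the samples split in other ways were set before the data were examined, and the gene lists below were fixed then too. Notch signalling genes were not called as a list in any comparison. Against progenitor, 1 of 12 was higher and 1 lower in stem (3 and 2 adjusted over the list alone, median -0.27 with the test pointing up, camera adjusted p = 0.953). Against niche, 2 were higher and 1 lower (2 and 2 adjusted over the list alone, median 0.31, adjusted p = 0.762), namely the transcription factor gene Rbpj (2.35 ± 0.46), the ligand gene Dll4 (2.20 ± 0.48) and the target gene Hes1 (-2.39 ± 0.48). Between progenitor and niche 1 of 12 was higher (median 0.49, adjusted p = 0.814). Stem and progenitor did not differ by the test in the mature neuron list (0 of 15 higher, 1 lower, median 0.01 with the test pointing down, adjusted p = 0.475), although Snap25 was lower (-1.77 ± 0.38), nor in the oligodendrocyte precursor (0 of 12 higher, 1 lower, adjusted p = 0.255), interneuron (0 of 6 higher, 1 lower, adjusted p = 0.285), LPA (0 of 7 higher, 1 lower, adjusted p = 0.255), complement (2 of 5 higher, 2 lower, adjusted p = 0.953), blood cell (0 of 5, adjusted p = 0.432), glycolysis (0 of 10 higher, 1 lower, median 0.12 with the test pointing down, adjusted p = 0.658) and mitochondrially encoded lists (0 of 12, adjusted p = 0.570).

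Between stem and niche, the MHC class I list (0 of 14, median 0.29, camera adjusted p = 0.480), the leukocyte list (2 of 22 higher, 2 lower, adjusted p = 0.338), the lysosome list (1 of 20 higher, 6 lower, adjusted p = 0.439), the complement list (1 of 5 higher, 2 lower, adjusted p = 0.129) and the ErbB list (2 of 7 higher, 1 lower, adjusted p = 0.727) were not called. Among the largest changes outside the lists were Grp (-5.14) and Synpr (-5.06). Htra1, a secreted protease of astrocytes, was at 7.95 ± 4.56 in stem and 319 ± 120 in niche (-5.20 ± 0.41). Between progenitor and niche, the mural list (0 of 10, adjusted p = 0.591), the ependyma list (2 of 8 higher, 2 lower, median 0.46 with the test pointing down, adjusted p = 0.958), the interferon list (2 of 26 higher, 3 lower, median 0.12 with the test pointing down, adjusted p = 0.859) and the lipid synthesis list (0 of 16, median 0.12 with the test pointing down, adjusted p = 0.859) were not called. The fibroblast list (4 of 12 higher, 2 lower, adjusted p = 0.0736) was called higher with only these 2 groups in the fit (0.0323) and without progenitor replicate 3 (0.0224), within a range of 0.0224 to 0.510 over the alternatives run for lists. The immediate early list (0 of 13 higher, 2 lower, adjusted p = 0.0807) was called lower with no filter (0.0327), with only these 2 groups in the fit (0.03235) and without progenitor replicate 2 (0.0114), 3 (0.0194) or 4 (0.0237), within a range of 0.0114 to 0.510. By library size alone the test passed too (0.0487), but with a median of 0.01 against 0.62 for all genes, so by that scaling the list was not lower in itself. The LPA list (1 of 7 higher, 2 lower, adjusted p = 0.0501) was called lower with a pseudocount of 4 RPKM (0.0448), without progenitor replicate 2 (0.0317), 3 (0.0415) or 4 (0.0310) or niche replicate 2 (0.0249), 3 (0.0278) or 4 (0.0422), within a range of 0.0249 to 0.140.

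Each comparison was repeated for all 35 splits of its 8 libraries into 4 and 4. Only the real split, 1 of 35, gave as many genes in each comparison. It called 594, 1806 and 955 genes, against at most 1, 1 and 55 in another split. A share below 1 of 35 cannot be reached. The other splits mix the populations, which widens the spread within each side and lowers their counts. Among the 8 splits that parted all pairs of equal replicate number, the highest others were 0, 1 and 11 genes, and among those that did not, 1, 1 and 55. With replicates taken as pairs the share is 1 of 8, so the splits alone do not exclude chance for the gene counts. For the number of lists called the splits cannot decide on chance, which is not excluded. As many lists were called in 12, 10 and 2 of the 35 splits. The real split called 17, 15 and 20, and another up to 22, 17 and 20 (up to 21, 15 and 19 among those parting all pairs). Nearly all other splits with as many lists kept 3 libraries of a population on the same side, and so part of the real difference. Splits with 2 libraries of each population per side called up to 13, 15 and 7 lists. For the genes set apart in stem from both other groups, 1 of 100 regroupings of the 12 libraries, the real one, gave as many, with 178 higher and 169 lower against at most 15 and 24. The other regroupings mix the populations too.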
